A study of Homo sapiens with 2 samples.

How the data were processed

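Strand-specific RNA sequencing libraries were made from liver progenitors derived from CyT49 human embryonic stem cells at day 8, per the labels. Messenger RNA was selected with oligo(dT) beads from 2 µg of total RNA, and the second cDNA strand was marked with dUTP and digested before amplification. Poly(A) selection limits the view of RNAs without a tail, and PCR without molecular identifiers means that reads are not independent molecules, so counting error is a lower bound of the technical error.

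The deposited table holds 57158 versioned Ensembl gene identifiers with 1 RPKM value per library, normalized by the authors to gene length and to the number of reads. The submitters' processing notes name FastQC 0.10.1, STAR 2.3.0e and Cufflinks 2.2.0 without saying which step each served, and the series description names Sailfish for expression levels and hg19 as the genome. Which of these tools gave the RPKM values, and the annotation release behind them, are not given in the sources used here. No raw reads were processed here. From the values alone, every number under 0.5 had been set to 0.1: none lay between 0.1 and 0.5 in either library, and 39548 genes in library 1 and 39542 in library 2 held 0.1. A value of 0.1 is therefore read as under 0.5 RPKM and is called the floor. Values of single-exon genes were multiples of a fixed step divided by gene length. Among those under 500 reads, 83.6% in library 1 and 83.8% in library 2 were whole within 0.02 of a read, and the step gives 25182071 and 25263820 reads in the normalization. Genes with several exons did not give whole reads, so no counts were reconstructed and no count model was used. Pseudogenes with reads of their parent gene, and RPKM that divides by 1 gene length whatever the isoform, can both shift single levels.

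The 2 libraries differed by 1.09 times the counting variance over 955 single-exon genes with whole read numbers and a mean of 50 reads or more. That lower limit was chosen after the values were seen, the ratio ran from 0.971 to 1.19 over 4 bins of depth, and 870 of the 955 genes are pseudogenes, which can share reads with a parent gene. In simulated libraries the ratio was 0.94 with counting alone and 5.35 with a spread of 10% added to each library. The libraries were therefore treated as 1 sample. Their descriptions end in different suffixes that may be lane numbers, but the labels do not explain them. Nor do the labels say whether the libraries came from separate cultures, RNA preparations or sequencing lanes.

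Identifiers were joined without their version to GENCODE release 44 mapped to GRCh37, the build also called hg19, and 54428 (95.2%) matched. Symbols, biotypes, positions and exon lengths come from that annotation. The background was 19344 protein-coding symbols with 1 value each, from the identifier of highest mean. A gene was called detected at 1 RPKM or more in both libraries, and levels were log2(RPKM + 1) averaged over the libraries.

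Before the data were examined, 44 gene lists with 716 symbols in all, 14 gene pairs, the tests, the alternatives and the rule for naming genes were fixed. Of the pairs, 13 had values, since a symbol of the remaining pair was not matched. The lists cover liver functions and stages, other lineages, yolk sac, signalling targets, metabolism and cell state, and none was chosen on these samples. Of the symbols, 710 were matched, 4 of them through an older symbol, and 6 were not, so they have no value here. GTL3 was matched as an older symbol of CFAP20, which is not known to be imprinted. ESRG, H19, MEG3 and KCNQ1OT1 are not protein-coding and were left out of the tests. Named genes are the 25 protein-coding genes highest by mean RPKM outside mitochondrial, ribosomal protein and small RNA genes, and up to 4 highest and 3 lowest members of each list described. They also include any member of the liver factor, pluripotency, endoderm and mature hepatocyte lists and both genes of each pair. The 10 protein-coding genes with the largest difference between libraries at a mean of 5 RPKM or more are named too. Any other gene was chosen after its values were seen. Some genes that the rule names are not reported here by name and are not drawn by name, while the counts and tests of their lists include them.

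Detection of each list was compared with all other background genes by Fisher's exact test, two-sided. The mean level of each list was compared with 100000 random lists of the same size from the background, and hepatic transcription factors with each lineage list, and hepatoblast with mature hepatocyte markers, by permutation tests of 100000 resamples, two-sided, with shared genes removed. Adjusted p-values are Benjamini-Hochberg over the 44 lists or the 16 lineage lists, with a threshold of 0.05. In these tests genes are the units, so they speak about lists of genes in 1 sample and not about repeated cultures. Comparison between groups was not possible with 1 group, and the published transcriptomes that the series description mentions were not used here. On shuffled values, 14 of 220 list tests of detection, 11 of 220 of level and 4 of 80 lineage contrasts had an unadjusted p under 0.05. A shift of 1 log2 unit added to a simulated list was recovered in 4 of 10 cases, and shifts of 2 and 3 in 10 of 10.

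Alternatives were detection limits of 0.5 and 5 RPKM, rescaling both libraries to the same sum with a limit of 1, a limma test of detection, pseudocounts of 0.1 and 0.01, quantile normalization, a background without genes at the floor, a background of every gene with a symbol, sums over the identifiers of a symbol, medians in place of means, and each library left out. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.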

Results

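Poly(A) RNA from liver progenitors derived from the human embryonic stem cell line CyT49 was profiled by strand-specific RNA sequencing. The cells had been brought to definitive endoderm, the germ layer that forms gut, liver and pancreas, by day 2. They were then kept in suspension for 6 days with 50 ng/ml BMP4 and 10 ng/ml FGF2, growth factors that induce liver fate in endoderm. The labels also give 0.2% FBS (serum), and the cells were collected at day 8. The series held 2 libraries of this 1 group, titled as replicates, and no untreated or earlier sample, so levels are described within the group and no change over time or with treatment could be measured. Values are RPKM (reads scaled to gene length in kilobases and to sequencing depth), with every value under 0.5 listed as 0.1. The step between values of single-exon genes corresponded to 25182071 reads in library 1 and 25263820 in library 2, so that 1 RPKM on a gene of 2000 bp stood for 50.4 reads in library 1. The libraries lay so close to counting error that they were counted as 1 sample. Values below are means of the 2 libraries unless both are given, and the difference between libraries is read as technical error, since the labels do not say whether the libraries came from separate cultures. Gene positions are on GRCh37 (hg19).

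The purpose named for the series was a genome-wide expression profile of these progenitors, and the question asked of the table was which genes and gene programs the cells expressed. The most abundant protein-coding transcript outside mitochondrial and ribosomal protein genes was APOA1, the main protein of high-density lipoprotein, at 2189 RPKM in library 1 and 2186 in library 2. It is ENSG00000118137.5, on chromosome 11 from 116706467 to 116708338. Among the 25 highest genes stood further secreted products of the liver, namely APOE at 1207 RPKM, FGB (fibrinogen beta chain) at 868, APOA2 at 812, TTR (transthyretin, the thyroid hormone and retinol carrier) at 776 and AFP (alpha-fetoprotein) at 706. DLK1, a surface protein of hepatoblasts, stood at 477 RPKM and MDK, the growth factor midkine, at 519. The matrix protein FN1 stood at 1794 RPKM, the iron storage chain FTL at 2066 and the chromatin protein HMGA1 at 499. Most of the rest of the 25 were broadly expressed genes of the cytoskeleton, translation, glycolysis and protein folding, among them ACTG1 at 1935, ACTB at 1698, EEF1A1 at 1582, TMSB10 at 1107, GAPDH at 1060 and EEF2 at 1018 RPKM. In all, 15020 of 57158 genes (26.3%) reached 1 RPKM in both libraries, and 11575 of 19344 protein-coding genes (59.8%) did, with a median protein-coding level of 2.42 RPKM. Protein-coding genes held 52.2% of the summed RPKM in library 1, pseudogenes 30.5% and mitochondrial genes 13.01%. Part of the pseudogene share came from copies of abundant genes, such as EEF1A1P5 at 5442 RPKM. Levels of genes with near-identical copies, and so the ranks given here with the first rank of APOA1 included, depend on how reads were shared out.

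Liver transcription factors were expressed, with 12 of 21 at 10 RPKM or more. The pioneer factor FOXA2 stood at 72.1 RPKM in both libraries, HHEX, which is needed for the liver bud, at 59.7, and HNF4A, the central regulator of hepatocyte genes, at 44.5 and 44.9. GATA4 stood at 43.4 RPKM, GATA6 at 42.6, CEBPA at 42.3, CREB3L3 at 40.4, FOXA1 at 39.7, FOXA3 at 36.4, TBX3 at 34.3, ONECUT1 at 19.9 and PROX1 at 14.6. NR5A2 at 3.84, PPARA at 3.36 and ONECUT2 at 1.33 RPKM were lower, NR1I3 was above the floor in 1 library only, and the nuclear receptors of bile acid and drug metabolism NR1H4, NR0B2 and NR1I2 were listed under 0.5 RPKM in both. HNF4A is ENSG00000101076.11, on chromosome 20 from 42984339 to 43061485. Of the 21 factors measured, 17 reached 1 RPKM, which was not called against other protein-coding genes after correction (Fisher's exact test, two-sided, adjusted p = 0.113). Their mean level was 1.63 higher on the log2(RPKM + 1) scale than that of other protein-coding genes (permutation test, two-sided, adjusted p = 0.00033). At a limit of 5 RPKM their detection also passed the exact test (adjusted p = 0.0434).

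Most genes listed as early hepatoblast markers were abundant, and those listed as mature hepatocyte markers were low or at the floor. Of 21 hepatoblast markers, 20 reached 1 RPKM (Fisher's exact adjusted p = 0.00139), with a median of 132 RPKM; APOA1, FGB, APOA2, TTR and AFP were the highest, and lower members included DLK1, KRT19 (409 RPKM), KRT8 (193), IGF2 (132) and EPCAM (123). ALB, the albumin gene, was among the lowest members at 6.84 RPKM in library 1 and 6.53 in library 2, and LGR5 was at the floor. Of 30 mature hepatocyte markers, 6 reached 1 RPKM (Fisher's exact adjusted p = 0.000124) and 22 were at the floor in both libraries. The 6 were the asialoglycoprotein receptor subunits ASGR2 (6.02 RPKM) and ASGR1 (2.79), ADH1B (5.37), the urea cycle enzymes CPS1 (4.06) and ARG1 (2.56), and TDO2 (3.06). CYP3A4, CYP2E1, CYP7A1, the rate-limiting enzyme of bile acid synthesis, TAT, G6PC, PCK1, the bile salt transporters SLC10A1 and ABCB11, and F9 were among those at the floor. The mean of the hepatoblast markers exceeded that of the mature markers by 6.41 on the log2(RPKM + 1) scale (permutation test, two-sided, p = 1e-05, the smallest that the resampling can give). The hepatoblast list also holds genes of the apolipoprotein, coagulation and plasma carrier lists, such as APOA1, FGB and TTR. Those lists are not defined by stage, so the contrast does not by itself give the stage of the cells. A gene listed at the floor may still be transcribed, since 0.5 RPKM on a gene of 2000 bp stood for 25.2 reads in library 1.

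**Figure D1:**
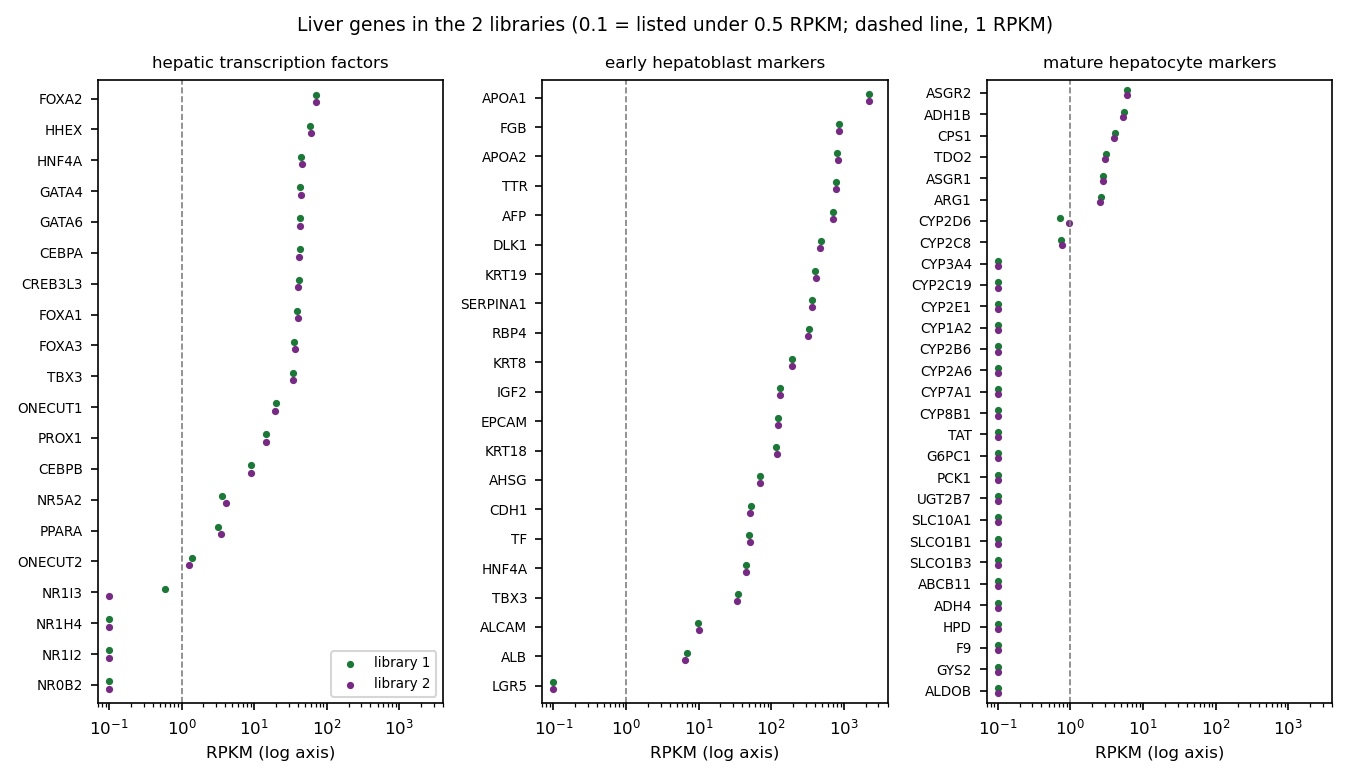
RPKM of hepatic transcription factors, early hepatoblast markers and mature hepatocyte markers (horizontal log axis, 1 row of points per gene) in library 1 and library 2, with the dashed line at 1 RPKM and values under 0.5 drawn at 0.1. To the right of the dashed line lie 6 mature hepatocyte markers and 20 of 21 early hepatoblast markers.

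The other liver lists differed by function. Apolipoproteins had a higher mean level than other genes (difference 2.47 log2, permutation adjusted p = 4.4e-05), with APOA1, APOE, APOA2 and APOC1 (227 RPKM) highest and APOA5, APOF and APOD at the floor, while detection of 10 of 15 members was not called (Fisher's exact adjusted p = 0.83). Of the coagulation and fibrinolysis factors, 12 of 22 reached 1 RPKM, led by the fibrinogen chains FGB, FGA (149 RPKM) and FGG (57.2) and by F10 (48.4), with KLKB1, KNG1 and HRG at the floor. Of the acute phase and plasma carrier proteins, 13 of 27 did, with TTR, SERPINA1 (365 RPKM), RBP4 (327) and VTN (247) high and HAMP, CRP and SAA1 at the floor. Neither list was called in detection (Fisher's exact adjusted p = 0.751 and 0.331) or level (permutation adjusted p = 0.116 and 0.0996). Complement components were detected less often than other genes, 5 of 19 (Fisher's exact adjusted p = 0.00923), with SERPING1 at 40.8 RPKM, C5 at 19.4 and C3 at the floor. Bile acid synthesis and transport genes were also detected less often, 4 of 18 (adjusted p = 0.0037 in the same exact test), the highest being AKR1D1 at 28.4 RPKM and CYP27A1 at 11.4. Phase I and II xenobiotic enzymes reached 1 RPKM in 4 of 24 cases (adjusted p = 0.000167 in the same exact test), and the 4 were GSTA2 (71.0 RPKM), GSTA1 (26.5), EPHX1 (18.1) and POR (14.7). Levels of these 3 lists were lower than those of other genes too (permutation adjusted p = 0.0146, 0.0209 and 0.02), while at a limit of 5 RPKM their detection calls were lost (exact adjusted p = 0.0562, 0.0859 and 0.104). The bile acid list also lost it at a limit of 0.5 RPKM (exact adjusted p = 0.135). Of the urea cycle and amino acid catabolism genes, 9 of 18 were detected, led by GLUD1 at 56.8 and ASS1 at 11.8 RPKM, and of the gluconeogenesis and glycogen genes 6 of 14 were, led by GYG2 at 17.9 and SLC37A4 at 16.6 RPKM. Cholangiocyte markers were detected in 11 of 16 cases, with KRT19, SOX4 (177 RPKM), ONECUT1 and SPP1 (17.4) highest and KRT7, SLC5A1 and SCTR at the floor. None of these last 3 lists was called in detection (Fisher's exact adjusted p = 0.577, 0.366 and 0.709) or level (permutation adjusted p = 0.268, 0.306 and 0.088).

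As lists, markers of the 16 other lineages tested stood below the liver factors in mean level. The yolk sac and visceral endoderm list was not among these contrasts. Its mean log2(RPKM + 1) of 4.88 lay above the 3.59 of the liver factors, and it includes genes that the liver lists also hold. After genes held by both lists were removed, hepatic transcription factors had a higher mean log2(RPKM + 1) than each of 16 lists of other lineages. The difference ran from 2.03 against septum transversum mesenchyme and stellate cells (permutation test, two-sided, adjusted p = 0.00382) to 3.44 against paraxial mesoderm and muscle (adjusted p = 3.2e-05). Against the mesendoderm list, 17 liver factors were left after removal. Against the pancreatic, intestinal and stomach lists all 21 stayed, among them FOXA2, HHEX, GATA4 and GATA6 of the mesendoderm list. The contrasts therefore do not by themselves tell liver from other endoderm. Of the 16 lists, 13 were detected less often than other protein-coding genes and the same 13 were lower in level, while pluripotency, mesendoderm and septum transversum were called in neither test. No stomach marker of 15 and no paraxial mesoderm marker of 18 reached 1 RPKM. When members at the floor in both libraries were left out, an alternative chosen after seeing the data, all 13 lists that could still be tested lay below the liver factors and 1 was called, endothelium (difference 2.89, permutation adjusted p = 0.012). In the others the difference was 1.02 to 2.70 log2 with fewer genes tested (permutation adjusted p = 0.0653 to 0.259).

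Among pluripotency genes, POU5F1, NANOG and SOX2, the core factors of stem cells, were at the floor in both libraries, as were LEFTY1, LEFTY2, PRDM14, DPPA2, FGF4, UTF1 and KLF4. LIN28A, an RNA-binding protein, stood at 129 RPKM, SALL4 at 24.6, ZFP42 at 13.1, DNMT3B at 12.6 and LIN28B at 8.56. In total 8 of 20 reached 1 RPKM (Fisher's exact adjusted p = 0.158). Among mesendoderm and definitive endoderm genes, 9 of 19 were detected (Fisher's exact adjusted p = 0.439). FOXA2, HHEX, GATA4 and GATA6, which the liver list also holds, were the highest, followed by KIT at 11.1, CXCR4 at 4.01, SOX17 at 2.85, WNT3 at 1.83 and PRDM1 at 1.65 RPKM, while the primitive streak genes T, EOMES, MIXL1 and GSC were at the floor.

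Single genes stood above most members of the other lineage lists. In the pancreatic list (6 of 21 detected, Fisher's exact adjusted p = 0.0131), PRSS1 (trypsinogen) had 60.2 RPKM, although its relatives PRSS3 (27.0), PRSS3P1 (41.4) and PRSS3P2 (31.7), named after their values were seen, can share its reads; the progenitor factor PDX1 had 8.44, SST 5.32 and RFX6 3.71 RPKM. In the trophoblast and amnion list (6 of 24, Fisher's exact adjusted p = 0.00177), CGA, the common alpha subunit of glycoprotein hormones, had 133 RPKM in library 1 and 138 in library 2, followed by TEAD4 at 10.5, GATA3 at 10.3 and GATA2 at 3.33. VIL1 at 30.0 RPKM and KLF5 at 6.23 led the intestine and hindgut genes (6 of 19, exact adjusted p = 0.0316), and TUBB3 at 39.6 and NES at 15.7 RPKM led neural ectoderm (4 of 21, exact adjusted p = 0.000623). ERBB3 at 16.0 RPKM was the highest of the neural crest markers (4 of 16 detected, exact adjusted p = 0.0169), SALL1 at 19.6 RPKM of the kidney markers (2 of 16, exact adjusted p = 0.000531) and KRT10 at 7.42 of the surface ectoderm markers (1 of 17, exact adjusted p = 5.42e-05). Cardiac mesoderm (7 of 21, exact adjusted p = 0.0411) was led by GATA4, NPPB at 12.8 and TBX20 at 10.1 RPKM, with TNNI1 and PLN at the floor. Septum transversum and stellate cell markers (9 of 22, exact adjusted p = 0.125) were led by VIM at 95.1, GATA4, PDGFRA at 18.2 and RGS5 at 17.8 RPKM. Endothelial markers (3 of 19, exact adjusted p = 0.000602) reached at most 5.75 RPKM, for ESAM, and blood and macrophage markers (3 of 23, exact adjusted p = 5.42e-05) at most 10.8, for EPOR. Of the lung, thyroid and anterior foregut markers 3 of 20 were detected (exact adjusted p = 0.000412), with TBX1 highest at 2.23 RPKM. At a limit of 5 RPKM the detection calls of the pancreatic, intestinal, neural crest and cardiac lists were lost (exact adjusted p = 0.113, 0.0562, 0.113 and 0.237). Yolk sac and visceral endoderm genes, in contrast, were detected more often than other genes, 19 of 22 (Fisher's exact adjusted p = 0.0279). Of these 22, 11 are also in a liver list, so the call rests in part on shared genes. Of the other 11, 8 reached 1 RPKM, beside 59.8% of all protein-coding genes, and these 11 were not tested on their own.

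**Figure D2:**
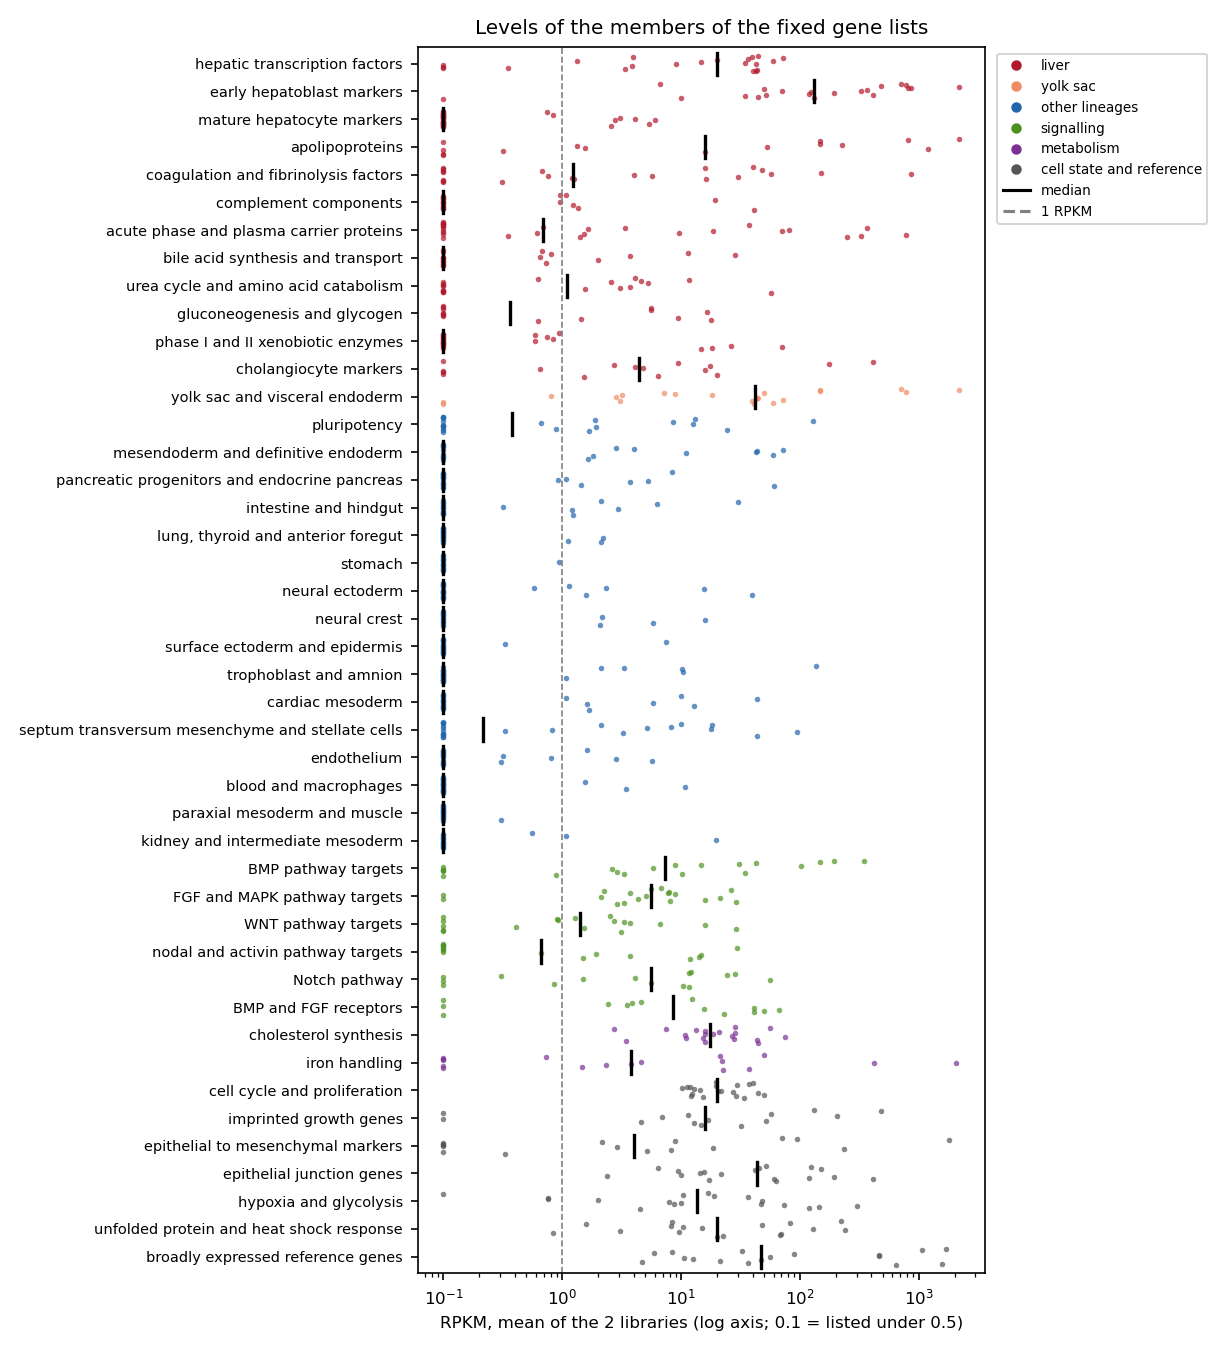
Mean RPKM of the 2 libraries (horizontal log axis) for every tested member of the 44 gene lists, 1 point per gene coloured by the class of its list, with a black bar at each list's median and a dashed line at 1 RPKM. Genes listed under 0.5 RPKM in both libraries are at 0.1; the median is 132 RPKM for early hepatoblast markers, 41.7 for yolk sac and visceral endoderm, and 0.1 for mature hepatocyte markers.

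The culture contained BMP4 and FGF2, the labels also give 0.2% FBS, and target genes of the BMP and FGF pathways were measured. Which of these the levels reflect was not tested. BMP targets were higher in level than other genes (difference 1.37 log2, permutation adjusted p = 0.00211). The helix-loop-helix inhibitors ID1 (347 RPKM), ID2 (192) and ID3 (148) and the decoy receptor BAMBI (102) were the highest, whereas GREM1, HAMP and HAND1 were at the floor, and detection of 14 of 20 was not called (Fisher's exact adjusted p = 0.588). FGF and MAPK targets were detected more often, 17 of 19 (Fisher's exact adjusted p = 0.0169), led by CCND1 at 28.8, the phosphatase DUSP5 at 26.2, EGR1 at 21.1 and IER3 at 16.0 RPKM, while their level was not called (difference 0.75 log2, permutation adjusted p = 0.088). BMP and FGF receptors were higher in level (difference 1.18 log2, permutation adjusted p = 0.0207), with FGFR3 at 66.4, FGFR4 at 49.8, FGFRL1 at 41.5 and FGFR1 at 41.1 RPKM. WNT targets (10 of 18 detected, led by CCND1 and by DKK1 at 15.9 RPKM), nodal and activin targets (7 of 15, with CER1, LEFTY1 and NODAL at the floor) and Notch pathway genes (10 of 15, led by HES1 at 56.1 and NOTCH3 at 28.6 RPKM) were called in neither test (Fisher's exact adjusted p = 0.83, 0.395 and 0.83; permutation adjusted p = 0.327, 0.396 and 0.264). At a limit of 5 RPKM the detection call of the FGF and MAPK targets was lost (exact adjusted p = 0.218), and with a pseudocount of 0.01 the level call of the receptors was lost (permutation adjusted p = 0.0527).

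Cell cycle and epithelial junction genes were all detected. All 20 cell cycle genes reached 1 RPKM (Fisher's exact adjusted p = 0.000219), among them PCNA at 49.8, MCM3 at 44.2, TOP2A at 40.7 and CCNB1 at 37.4 RPKM. All 18 epithelial junction genes did too (Fisher's exact adjusted p = 0.000531), with KRT19, KRT8, CLDN6 (151 RPKM) and EPCAM highest. Genes named for the epithelial to mesenchymal transition were higher in level (difference 1.13 log2, permutation adjusted p = 0.0181), carried by FN1, SPARC (235 RPKM), VIM and CDH2 (71.2), whereas ZEB2, TWIST2 and COL3A1 were at the floor and detection of 10 of 16 was not called (Fisher's exact adjusted p = 1). With a pseudocount of 0.1 that level call was lost (permutation adjusted p = 0.102). All 20 cholesterol synthesis genes were detected (Fisher's exact adjusted p = 0.000219), among them HMGCS1 at 55.5 and SREBF2 at 44.7 RPKM. Unfolded protein and heat shock genes were detected in 16 of 17 cases (Fisher's exact adjusted p = 0.00604), led by the chaperones HSP90B1 at 237 and HSPA5 at 221 RPKM. Hypoxia and glycolysis genes were higher in level (difference 2.07 log2, permutation adjusted p = 4.4e-05), with ENO1 at 302, ALDOA at 144 and P4HA1 at 119 RPKM and CA9 at the floor, while detection of 15 of 18 was not called (Fisher's exact adjusted p = 0.0892) but was called at limits of 0.5 and 5 RPKM (exact adjusted p = 0.0127 and 0.0063). Imprinted growth genes were likewise higher in level (difference 2.43 log2, permutation adjusted p = 4.4e-05) and not called in detection (12 of 14, Fisher's exact adjusted p = 0.0925), led by DLK1, CDKN1C at 204 and IGF2 at 132 RPKM. Iron handling genes were higher in level (difference 1.18 log2, permutation adjusted p = 0.0119), with FTL, FTH1 (422 RPKM) and TF (50.2) highest and CP, HFE and HP at the floor, and detection of 11 of 17 was not called (Fisher's exact adjusted p = 0.83). With a pseudocount of 0.1 the level call of the iron genes was lost (permutation adjusted p = 0.059). All 17 broadly expressed reference genes were detected (Fisher's exact adjusted p = 0.000694), among them ACTB, GAPDH and EEF1A1. Counted over the 44 lists, 8 were detected more often than other protein-coding genes, 17 less often and 19 were not called, and when genes at the floor in both libraries were left out of lists and background alike, these became 0 more often and 1 less often, the xenobiotic enzymes. In level, 15 lists were higher and 17 lower, and without genes at the floor 15 were higher and 1, endothelium, was lower. The 15 were not all the same lists, since BMP and FGF receptors lost their call (permutation adjusted p = 0.0544) and acute phase and plasma carrier proteins gained one (permutation adjusted p = 0.00322).

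Pairs of genes compared early with late or related functions within each library. AFP, the fetal serum protein, exceeded its chromosome 4 neighbour ALB by 103-fold in library 1 and 108-fold in library 2. AFP (ENSG00000081051.3) lies from 74296855 to 74321891 and ALB (ENSG00000163631.12) from 74262831 to 74287199. DLK1 exceeded CPS1 by 117-fold, EPCAM exceeded ASGR1 by 44.3-fold and IGF2 exceeded ALB by 19.7-fold, as ratios of mean RPKM. LIN28B was at least 17.1-fold above TAT, taking TAT at the 0.5 RPKM below which values were not listed. ONECUT2 stood at 0.0665 of ONECUT1, CEBPB at 0.212 of CEBPA and AFP at 0.323 of APOA1. KRT19 was 2.11 times KRT8, CDH2 was 1.37 times CDH1, FGFR1 was 0.825 of FGFR4 and GATA6 was 0.981 of GATA4. CYP3A7 and CYP3A4 were both at the floor, so no ratio was formed. On the log2(RPKM + 1) scale the SD of these differences over the 2 libraries was at most 0.047, for IGF2 over ALB. The ratios were not tested.

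The difference between the libraries gave the part of the technical error of each level that varies between them. Errors that both libraries share are not in it. Genes at or above 200 RPKM differed by a median of 0.928% of their mean, genes of 10 to 50 RPKM by 2.37% and genes of 1 to 2 RPKM by 8.24%. Of the 15020 genes at or above 1 RPKM, 140 were more than 1.5-fold apart and 16 more than 2-fold. Across all 57158 genes, which are not independent replicates, Pearson's r of log2(RPKM + 1) was 0.998 and Spearman's rho 0.979, and the many genes at the floor contribute to both. Among 955 single-exon genes with whole read numbers and a mean of 50 reads or more, the variance between libraries was 1.09 times the counting variance (chi-square p = 0.0271). Differences of single genes were ranked among protein-coding genes with a mean of 5 RPKM or more, and other classes of gene were not ranked. The largest were for PIGY at 12.3 and 17.2 RPKM and a transcript with no symbol (ENSG00000249141) at 7.95 and 5.96 in libraries 1 and 2. Next came RGS2 at 9.68 and 7.48, AL136376.1 at 4.55 and 5.94, CCDC85B at 7.91 and 6.18, and ING2 at 10.7 and 8.67. The last were ENSG00000260643 at 5.40 and 6.75, DDIT3 at 9.29 and 7.51, S1PR2 at 9.76 and 7.91, and F3 at 5.12 and 6.37. No liver factor or hepatoblast marker was among these 10.

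**Figure D3:**
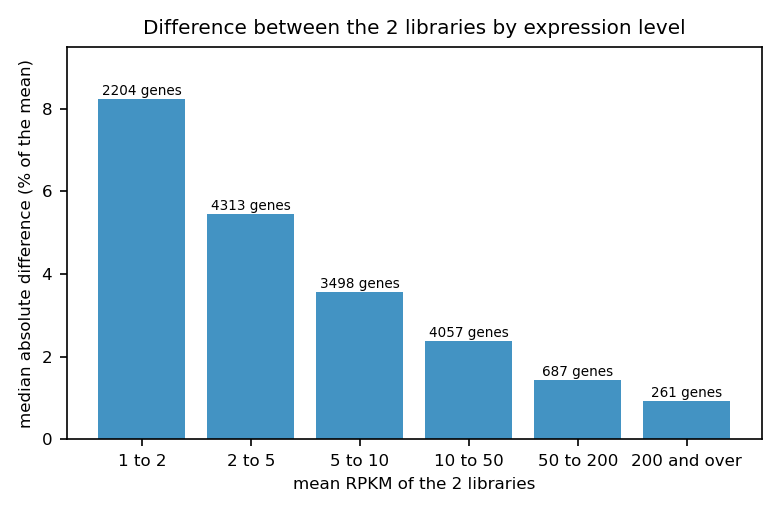
Median absolute difference between the 2 libraries as a percent of their mean (vertical axis, from 0) for genes grouped by mean RPKM (horizontal axis), with the number of genes above each bar. The bars fall from 8.24% at 1 to 2 RPKM to 0.928% at 200 RPKM and over.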

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

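Of the alternatives here, the one that leaves out list members at the floor was chosen after seeing the data, and the others were planned. No paired analysis was possible because the series has 1 group. Without either library in turn, 15317 to 15323 genes were detected, the 8 and 17 lists called by detection, the 15 and 17 called by level and the 16 lineage contrasts gave the same counts, and the hepatoblast minus mature difference was 6.40 to 6.41 log2. That difference ran from 5.45 to 8.80 over all its alternatives. A limit of 0.1 RPKM was not run as a test because every gene passes it, and leaving out members under 0.1 RPKM removes none. Genes under 0.5 RPKM cannot be ranked, because the deposited values replace them by 0.1, and depth limits the precision of genes just above. Genes detected numbered 17101 at 0.5 RPKM, and 14564 in the limma test, of which 11320 were protein-coding. Rescaling gave 17101 as well. It raised every value, so that a limit of 1 passed every gene above the floor. That count therefore could not differ from the count at 0.5 RPKM. Pearson's r between libraries was 0.992 to 0.998 over both pseudocounts, quantile normalization and genes at or above 1 RPKM.

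With a limit of 5 RPKM, 8362 genes were detected and 10 lists were detected less often. With genes at the floor left out of the background and the lists, 0 lists were detected more often, 1 less often and 1 was lower in level, because fewer genes were tested and most of them pass 1 RPKM. With every gene with a symbol as background, which adds noncoding genes and pseudogenes that are mostly at the floor, 20 lists were detected more often, 2 less often and 1 was lower in level. With list members at the floor left out, 1 lineage list was called below the hepatic factors, while all 13 testable lists lay below them, by 1.02 to 2.89 log2, with fewer genes tested.

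Directions that reversed are given as percentage points of detection, or log2 level, above other genes. At 0.5 RPKM, WNT targets were at 1.58 points and epithelial to mesenchymal markers at -2.59. At 5 RPKM, coagulation factors were at 5.49 and gluconeogenesis at 0.293. Without genes at the floor, detection reversed for mesendoderm (9.57), lung and foregut (9.57), neural crest (9.57), trophoblast (9.57), cardiac mesoderm (9.57), blood (9.57), Notch genes (-7.11) and hypoxia (-2.20), and level for mesendoderm (0.86), trophoblast (0.25) and septum transversum (0.27). With every gene as background, detection reversed for coagulation (27.0), acute phase (20.6), urea cycle (22.5), gluconeogenesis (15.3), pluripotency (10.6), mesendoderm (19.8), pancreas (1.05), intestine (4.05), cardiac mesoderm (5.81), septum transversum (13.4), WNT (28.0) and nodal targets (19.1). In that setting level reversed for urea cycle (0.47), gluconeogenesis (0.45), xenobiotic enzymes (0.063), pluripotency (0.45), mesendoderm (0.87), cardiac mesoderm (0.027), septum transversum (0.67), WNT (0.54) and nodal targets (0.57). Among the other values of single lists, contrasts and pairs under all alternatives, 614 kept direction and call. Another 87 kept direction and lost the call, and 22 gained one. The log2 differences of 9 pairs moved by more than their SD at each of the 2 other pseudocounts. Apart from the effect of a changed background, the cause of these changes was not tested. The 614 include every value without either library and with sums over identifiers. Libraries so close to counting error could change little when left out, so the 614 do not measure robustness.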

Other observations

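All tests of gene families and of explanations in this part were chosen after the values were seen, the 10 families from a larger number of symbol patterns looked at. In the HOX clusters, whose genes pattern the trunk, 0 of 39 genes were detected and 39 were at the floor, under 0.5 RPKM (Fisher's exact adjusted p = 1.67e-15 over 10 families). Of 55 keratins 4 were detected, namely KRT19 at 409, KRT8 at 193, KRT18 at 119 and KRT10 at 7.42 RPKM (exact adjusted p = 1.67e-15). Of 56 cytochromes P450, 9 were detected (exact adjusted p = 1.03e-10), with CYP4X1 at 12.5, CYP27A1 at 11.4 and CYP51A1 at 10.8 RPKM highest. The germline type I MAGE genes were at the floor in 25 of 25 cases (exact adjusted p = 3.04e-10), whereas 8 of 9 type II MAGE genes were detected (exact adjusted p = 0.135), led by MAGED1 at 86.2 RPKM.

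Of 18 type IV collagen and laminin genes, 9 were detected (exact adjusted p = 0.525): the collagen chains COL4A1 (82.3 RPKM), COL4A2 (84.7), COL4A5 (33.6) and COL4A6 (42.1), and the laminin chains LAMA1 (48.3), LAMA5 (16.9), LAMB1 (122), LAMB2 (20.1) and LAMC1 (54.8). Of 7 IGF binding proteins 6 were detected (exact adjusted p = 0.318), with IGFBP5 at 79.8 RPKM and IGFBP1, which adult hepatocytes secrete, at the floor. Of 11 SERPINA genes 6 were (exact adjusted p = 0.764), with SERPINA1 at 365 and SERPINA5 at 108 RPKM, and of 24 claudins 9 were (exact adjusted p = 0.0589), with CLDN6 at 151 RPKM. Other high genes outside the lists were GPC3, a fetal liver proteoglycan, at 461 RPKM, the glucose transporter SLC2A3 at 377, whose near copy SLC2A14 stood at 56.3, the neuropeptide NPY at 333, S100A14 at 306 and HABP2 at 95.7. The noncoding imprinted transcripts H19 and MEG3 stood at 243 and 32.4 RPKM. Of 82 ribosomal protein genes 2 were at the floor, RPL3L and RPL10L, and of 13 RNA polymerase II subunits 0 were.

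The 2 libraries differed by little more than counting noise. RPKM values copied from one library to the other after normalization are argued against, since 0.0% of the 17101 genes above the floor in both held the same value in both. This comparison does not cover reads shared before normalization, because the libraries were scaled by different read numbers. Whether 1 RNA pool or library was measured in 2 lanes, or cultures grown side by side were, cannot be told apart, because the variance ratio of 1.09 was not set against that of cultures known to be separate. No biological explanation was tested for this pattern.

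CGA stood at 136 RPKM while the next highest member of the trophoblast and amnion list, TEAD4, stood at 10.5. Genes outside that list were not weighed. Of the 23 other markers 5 were detected and 18 were at the floor, less often than other protein-coding genes (Fisher's exact p = 0.000349), but their low level is part of the pattern, so trophoblast or amnion cells in the culture stay open as a source. A whole glycoprotein hormone program is argued against, with 0 of 9 beta subunit genes above the floor (exact adjusted p = 0.000542). Expression of the alpha subunit alone by the liver progenitors may account for the signal, a hypothesis that was not tested.

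ALB stood 106-fold below AFP, its neighbour on chromosome 4. Division by gene length is argued against, since the exon length of ALB is 1.07 times that of AFP. Late liver genes as a set were low as well: without AFP and ALB, 19 early markers exceeded 30 mature markers by 6.49 log2, which restates the stage contrast of the report and so decides nothing about ALB. An early stage of the cells may account for the low ALB, a hypothesis that stays open, since the series holds no later sample.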
